A study of Mus musculus with 10 samples.

How the data were processed

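RNA sequencing of Hepa1-6 cells, a mouse hepatoma line, was analysed in 10 libraries. Per the labels, 5 libraries came from untreated cells and 5 from cells kept for 48 h with CD8+ T cells, which had been isolated from mouse spleen and activated for 5 days with antibodies against CD3 and CD28 at a dilution of 1 in 2000. Suspended cells and debris were rinsed off with PBS before RNA extraction, and 1.3 ug of total RNA went into each library, made with the VAHTS Universal V6 kit, per the labels' protocols. Whether the RNA of 1 group's libraries came from separate cultures is not stated, so p-values measure only the spread between these libraries.

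The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.5 and RSEM 1.2.8 and the mouse build mm10, without the role of each tool. The annotation release and whether counting used strand are not given in the sources used here. The deposited table holds 34745 genes with their Ensembl identifiers, symbols and positions, 10 columns of FPKM and 10 columns of counts, per the file headers. The deposited counts are whole numbers and were not normalized. The deposited FPKM (fragments scaled to gene length and library total) were checked against the counts over 9379 genes with at least 100 counts in every library. The gene length implied by both units differed between libraries by at most 0.00104%, so the FPKM are the same counts divided by 1 fixed length per gene and by the library total. No value column was left unused. Of the identifiers, 98.8% were found in GENCODE M21 and 79.9% had the same position there. Positions are therefore given as the deposited table gives them. A symbol carried by several identifiers, which was the case for 59 symbols, was matched through GENCODE names. Reads shared by near-identical genes could have been split or dropped at counting, so values of the H2, Ifit, Gbp, Irgm, Tgtp, Oas and Serpina3 families and of Csf2rb with Csf2rb2 are uncertain in their split. Overlapping and antisense genes cannot be told apart where strand was not used.

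Totals ran from 12922263 to 17100662 counts per library. In 1 library, 3 counts, the limit that a count of 0 allows, corresponded to 0.175 to 0.232 CPM, counts scaled to the library total. Over the summed libraries of a group this floor was 0.0388 CPM for untreated cells and 0.0405 CPM for co-cultured cells. It was used for folds against a gene at 0 in all 5 libraries of a group. For 1 to 3 counts, the ratio of the summed counts is given with an exact 95% binomial interval. Floors and intervals cover counting error only.

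Replicate libraries were compared before averaging. Over the 20 pairs within a group, the chi-square per degree of freedom across genes was 6.72 to 15.5, so no pair agreed within sampling noise and each library was kept as 1 replicate.

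Differences between groups were tested on the counts with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling and the two-sided quasi-likelihood F test. 12666 genes were tested and Benjamini-Hochberg adjusted p-values under 0.05 were called. Every log2 fold change is co-culture over untreated, and every CPM in a gene comparison is TMM-scaled, with the SD over 5 libraries. Standard errors were derived from the log2 fold change and the F statistic. The test was tried on simulated counts for 12559 genes drawn from the means, dispersions and totals of these 10 libraries, with 200 genes changed, of which those that passed the filter were tested. It recovered 46 of 67 genes changed 1.5-fold, 62 of 65 changed 2-fold and 65 of 65 changed 4-fold, and 4.42% of its calls were false. The total per library, which was in the fixed design, and 4 other library measures, which were not, were compared by two-sided exact permutation tests over 252 arrangements, whose smallest possible p is 0.00794.

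21 gene lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, were run beside it. The lists, the tests of genes and lists, the alternatives except the other scalings for the list results, and the rule for named genes were fixed before the data were examined. That rule took 3 kinds of genes. The first were the 8 largest rises, the 8 largest falls and the 8 largest rises from at least 1 CPM in untreated cells, among called genes with a change of at least 2-fold, a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a predicted model. The second were the 2 members of each list with the smallest p, and the third were Cd274, B2m, Fas, Alb, Afp, Cd3e, Cd8a, Gzmb and Ifng. All other genes named were chosen after their values were seen. A few of the genes so chosen, by the rule or later, are not named in the text but remain in the counts of named genes under the alternatives. 6 further lists and 8 lineage panels were written later. They are given in the closing section, and the macrophage and neutrophil panels in the report as well.

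The alternatives were other scaling factors (median of ratios, upper quartile, and TMM from genes expressed in untreated cells), other low-count filters, testing only genes with at least 1 CPM in untreated cells, DESeq2 1.42.0 with its independent filtering, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, and each library left out in turn. Of the 126 splits of the 10 libraries into 5 and 5, 100 were tested in the same way.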

Results

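The data were gene counts from 10 RNA sequencing libraries of the mouse hepatoma line Hepa1-6, 5 from untreated cells and 5 from cells co-cultured for 48 h with activated CD8+ T cells, the lymphocytes that kill tumour cells. The comparison asks how expression in the cells left after the PBS rinse differs after 48 h with these T cells. Killing was not measured in these data. Totals per library were 15461200 ± 1510390 counts in untreated cells and 14797200 ± 1310550 after co-culture (SD, n = 5), a difference within the spread between libraries (two-sided exact permutation test, p = 0.468, adjusted p = 0.468 over 5 library measures). Ribosomal protein genes took 4.62% ± 0.0764 of the counts in untreated cells and 3.84% ± 0.285 after co-culture (n = 5, exact permutation p = 0.00794, the smallest the design allows, adjusted p = 0.0397). Mitochondrial genes took 2.90% ± 0.269 and 3.35% ± 0.182 (exact permutation p = 0.0317), which did not pass after adjustment (adjusted p = 0.0661). Detected genes numbered 15902 ± 179 and 16169 ± 157 (n = 5, exact permutation p = 0.0397, adjusted p = 0.0661), and the 10 most abundant genes held 6.31% ± 0.203 and 6.06% ± 0.141 of the counts (n = 5, exact permutation p = 0.0714, adjusted p = 0.0893).

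After co-culture, antiviral interferon-stimulated genes were lower in the hepatoma cultures, whereas the lists of cell cycle genes, NF-kappaB response genes and other leukocyte markers were higher. Ifit3, an interferon-induced antiviral gene, fell from 106 ± 24.8 to 7.66 ± 1.16 CPM (counts scaled to the library total). Angptl4, a secreted inhibitor of lipoprotein lipase, rose from 39.2 ± 4.13 to 297 ± 25.6 CPM, and Thbs1, the matrix glycoprotein thrombospondin, rose from 22.9 ± 3.07 to 75.3 ± 3.82 CPM. Lyz2, the lysozyme of macrophages and granulocytes, rose from 0.931 ± 0.25 to 18.2 ± 2.15 CPM (SD, n = 5 in each group). In all, 2204 genes were higher and 2044 lower after co-culture among 12666 tested (edgeR quasi-likelihood test, adjusted p below 0.05), and 151 of the rises and 200 of the falls were at least 2-fold. Every co-culture library lay above every untreated library for 1598 genes and below for 1412, where chance gives 0.794% of genes in both directions together. The count of 151 rises of at least 2-fold moved to 52 when only genes with at least 1 CPM in untreated cells were tested, to 330 without a low-count filter and to 27 with limma on log2(FPKM + 1), and the 200 falls moved to 72 with the last of these. Of the 21 fixed gene lists, 10 were called (camera, adjusted p below 0.05), against 5 with an estimated correlation and 17 with fry. Genes named below beyond the largest changes, the 2 members of each list with the smallest p and 9 genes fixed beforehand were chosen after their values were seen.

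**Figure D1:**
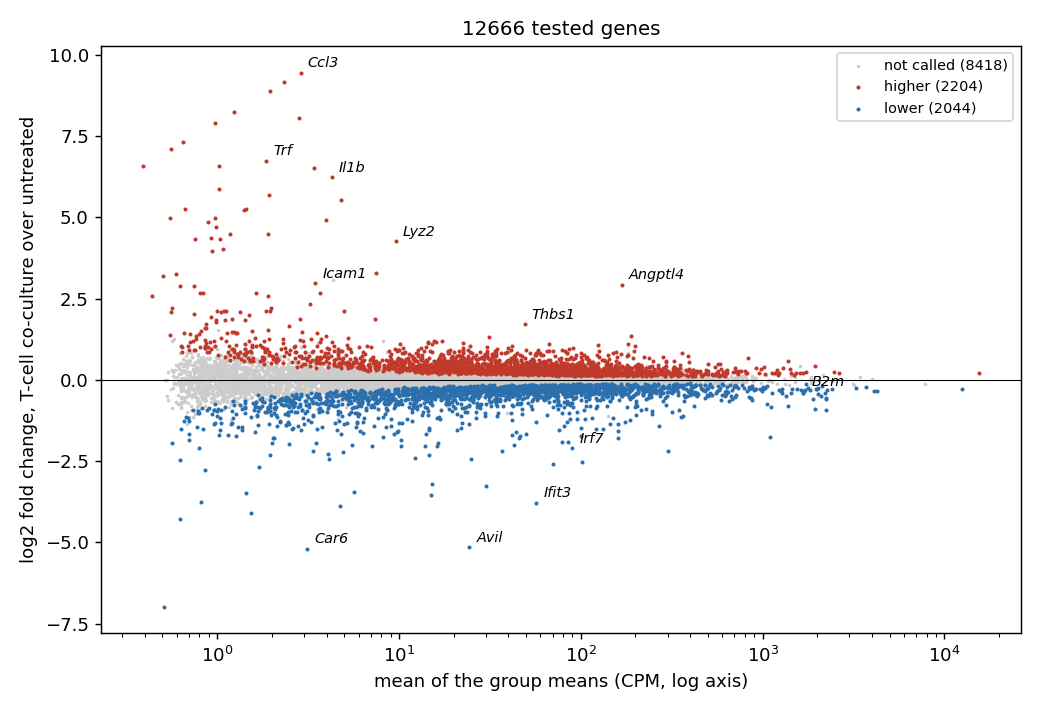
Log2 fold change of each of the 12666 tested genes (vertical axis, co-culture over untreated, edgeR) against its mean abundance in CPM (horizontal log axis), with 2204 genes called higher in red, 2044 called lower in blue and the other 8418 in grey. Ccl3 and other genes near 0 CPM in untreated cells make up the upper left, and Avil and Ifit3 lie among the lowest points.

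Antiviral interferon-stimulated genes were lower after co-culture. Of 27 antiviral interferon-stimulated genes, 26 fell and none rose, over all genes and adjusted over the list alone, with a median log2 fold change of -1.73. Ifit3 (chromosome 19, 34583531 to 34588731 in mm10) had a log2 fold change of -3.78 ± 0.159 (SE, edgeR adjusted p = 4.92e-09), and its near-identical copy Ifit3b fell by 3.54 on the log2 scale. Usp18, which removes the ubiquitin-like modifier Isg15 from proteins, fell from 154 ± 14.5 to 46.3 ± 2.14 CPM (n = 5, edgeR adjusted p = 2.00e-09), and Isg15 itself went from 497 to 109 CPM. The exception was Ifi27, at -0.08 (edgeR adjusted p = 0.296). The list was lower by camera (adjusted p = 2.79e-26, and adjusted p = 0.0440 with an estimated correlation). All 15 tested interferon-inducible GTPases, which act against intracellular pathogens, fell as well, with a median of -1.31. Irgm2 went from 122 ± 14.5 to 52.5 ± 2.89 CPM and Gbp3 from 70.5 ± 14.0 to 20.4 ± 1.22 CPM (n = 5). Their list was lower by camera (adjusted p = 3.68e-14) and missed the threshold with an estimated correlation (adjusted p = 0.0641).

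Among 18 genes of interferon receptors and JAK-STAT signalling, 5 fell and 4 rose. Irf7, the transcription factor that amplifies type I interferon production, fell from 145 ± 17.9 to 33.9 ± 2.63 CPM (log2 fold change -2.10 ± 0.0864 SE, edgeR adjusted p = 4.39e-09). Stat2 (-1.03), Irf9 (-0.81) and Jak2 (-0.32) also fell. The rises were small, Socs3 at 0.34, Ifngr1 at 0.22, Ifnar1 at 0.18 and Ifngr2 at 0.17. Irf1, a primary target of interferon gamma, was at 74.6 CPM in untreated cells and 73.5 CPM after co-culture (edgeR adjusted p = 0.836). The list as a whole was not called (camera, median -0.08, adjusted p = 0.0773). The call of Ifngr1 was lost in 5 of the 10 fits that left out 1 library, with adjusted p between 0.0169 and 0.0768. That of Ifngr2 was lost without the low-count filter (edgeR adjusted p = 0.0510) and with the replicate number as a block (edgeR adjusted p = 0.0653).

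Genes of MHC class I antigen presentation, which display peptides to CD8+ T cells, were modestly lower. Of 19 tested, 15 fell and none rose (16 fell when adjusted over the list alone), with a median of -0.35. The nonclassical genes H2-T23 and H2-T22 had the smallest p-values, H2-T23 going from 503 ± 33.0 to 231 ± 14.8 CPM and H2-T22 from 531 ± 19.3 to 306 ± 13 CPM (n = 5). The classical genes H2-K1 and H2-D1 fell by 0.55 and 0.29 on the log2 scale, and the peptide transporter gene Tap1 by 0.82. B2m, the light chain of class I molecules, went from 1896 ± 306 to 1484 ± 146 CPM (log2 fold change -0.35 ± 0.101 SE, edgeR adjusted p = 0.0159). Calr, Pdia3, Erap1 and Tap2 did not pass. The list was called lower by camera (adjusted p = 5.91e-08), and the call was lost with an estimated correlation (adjusted p = 0.0791). Without 1 library Tap2 passed in 2 of the 10 fits and Erap1 in 1, with lowest adjusted p of 0.0447 and 0.0355. MHC class II genes were mostly too low to test, and 4 of 9 were tested. Among the others, H2-Aa had 1 and 11 summed counts, a ratio of 11.5 (95% interval 1.67 to 495). H2-Ab1 had 2 and 18, a ratio of 9.40 (2.25 to 83.6), and H2-Eb1 had 0 and 15, at least 5.22-fold higher. Ciita had 0 in both groups, and H2-DMb1 had 43 and 57. Ctss, a lysosomal protease of antigen-presenting cells, rose from 0.433 ± 0.213 to 2.82 ± 0.212 CPM, Ifi30, a lysosomal thiol reductase, from 122 ± 2.09 to 171 ± 8.37 CPM (n = 5), and Cd74 by 0.44 on the log2 scale, while H2-DMa fell by 0.99. The macrophage genes Lyz2 and Adgre1 also rose after co-culture, by 4.27 and 4.47, and a shared source was not tested. The list was not called (camera, median 0.47, adjusted p = 0.0664).

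Ligands and other genes of immune evasion were lower on balance. Of 17 tested, 8 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.21. Cd274, the gene of the checkpoint ligand PD-L1, fell from 11.9 ± 1.47 to 7.03 ± 0.584 CPM (n = 5, log2 fold change -0.76 ± 0.102 SE, edgeR adjusted p = 9.20e-05). Lgals9, a galectin that binds inhibitory receptors of T cells, fell from 424 ± 34.2 to 214 ± 11.3 CPM, Cd47 by 0.46 and Ido1 by 1.27 on the log2 scale. Serpina3g, a serine protease inhibitor, was the member that rose, from 88.1 ± 4.46 to 164 ± 9.37 CPM. The list was lower by camera (adjusted p = 0.00112, and adjusted p = 0.0350 with an estimated correlation).

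NF-kappaB response genes were higher. Of 18 tested, 12 rose and none fell (14 rose and 1 fell adjusted over the list alone), with a median of 0.25. Icam1, an adhesion molecule for leukocytes, rose from 0.789 ± 0.222 to 6.15 ± 0.663 CPM (log2 fold change 2.98 ± 0.180 SE, edgeR adjusted p = 7.49e-08), and the pathway inhibitor gene Nfkbie rose from 41.4 ± 1.96 to 71.0 ± 3.42 CPM (n = 5). The negative regulators Tnfaip3 and Nfkbia rose by 1.11 and 0.59, and the adhesion gene Vcam1 by 0.59. The macrophage gene Lyz2 also rose after co-culture, by 4.27, and a shared source was not tested. The list was higher by camera (adjusted p = 6.52e-05, and adjusted p = 0.0440 with an estimated correlation). When only genes with at least 1 CPM in untreated cells were tested, Icam1 dropped out. The other 17 genes were still called higher (camera adjusted p = 0.000282), so the call did not rest on genes near 0 in untreated cells.

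Chemokine and cytokine genes went both ways, with 8 of 20 higher and 5 lower. Il1b, the inflammatory cytokine interleukin-1 beta, rose from 0.104 ± 0.0528 to 8.44 ± 0.426 CPM (n = 5, log2 fold change 6.22 ± 0.199 SE, edgeR adjusted p = 4.60e-10). Ccl9 rose from 1.38 ± 0.354 to 13.7 ± 1.33 CPM and Cxcl2, a neutrophil attractant, from 1.08 ± 0.464 to 5.41 ± 0.504 CPM. Tnf had 0 counts in all untreated libraries and 146 after co-culture, at least 50.9-fold higher over the summed libraries. The interferon-induced chemokine gene Cxcl10 fell from 65.9 ± 15.6 to 21.7 ± 1.89 CPM (n = 5), Cxcl9 and Cxcl11 fell by 1.65 and 0.99 on the log2 scale, and Il18 and Vegfa fell by 0.84 and 0.72. The list was not called (camera, median 0.11, adjusted p = 0.325). The rises of Il1b, Ccl9, Cxcl2 and Tnf went along with those of the leukocyte genes described next, and a shared source was not tested.

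Some genes known from myeloid leukocytes rose from near 0 in untreated cells, and others did not. Of a macrophage panel written after the main results, 8 of 15 tested genes rose and 1 fell (camera adjusted p = 0.000399, and adjusted p = 0.0171 with an estimated correlation). Only 3 of the 12 genes of a neutrophil panel, also written later, could be tested, and all 3 fell (camera adjusted p = 0.00298, and adjusted p = 0.0282 with an estimated correlation). Some genes of these panels were abundant without co-culture, such as Padi4 at 231 to 263 CPM and Itgb2 at 156 to 183 CPM in untreated libraries. Changes of such genes say little about RNA from other cells. The 8 largest rises among genes with a mean of at least 1 CPM all began from at most 5 counts over the untreated libraries. Ccl3, a chemokine gene of activated leukocytes (chromosome 11, 83647844 to 83649355), went from 0 to 432 summed counts, at least 150-fold higher. Chil3, a chitinase-like protein of macrophages, was at least 122-fold higher, Mmp8, a neutrophil collagenase, at least 102-fold and Csf2rb, a cytokine receptor chain, at least 64.4-fold. The chemokine gene Ccl6 had 1 and 423 summed counts, a ratio of 442 (95% interval 78.9 to 17498), and the lectin receptor gene Clec4e 1 and 151, a ratio of 158 (27.9 to 6273). Clec4n, another lectin receptor gene, rose from 0.0686 ± 0.0538 to 6.72 ± 1.14 CPM (n = 5). From at least 1 CPM, the phosphatase gene Inpp5d, the transporter gene Slc15a3 and Irg1, which makes itaconate, rose by 1.67, 1.87 and 2.13 on the log2 scale. Of the 21 other leukocyte markers (B cells, NK cells, CD4+ T cells, monocytes and macrophages), 6 could be tested and 4 rose (5 adjusted over the list alone). These were Lyz2, Adgre1, a macrophage surface gene that went from 0.162 ± 0.102 to 3.66 ± 0.482 CPM, Csf1r (1.76) and Cd14 (0.61), while Cd68 was at 0.01 (edgeR adjusted p = 0.968) and Flt3 at 0.75 and just short of the threshold (edgeR adjusted p = 0.05001). The list median was 1.26 (camera adjusted p = 0.000545, and adjusted p = 0.0350 with an estimated correlation). When only genes with at least 1 CPM in untreated cells were tested, Lyz2, Adgre1, Csf1r and Flt3 dropped out and the call ended (camera adjusted p = 0.28). Flt3 passed in 3 of the 10 fits without 1 library (adjusted p 0.0320 to 0.127) and in 5 of 10 other settings.

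Most marker genes of T cells were not detectable or near the floor, while a few, such as Lck, Coro1a and Ccl5, were well above it in both groups. Cd3e, Cd8a and Ifng had 0 counts in all 10 libraries, which allows up to 0.0388 CPM in untreated and 0.0405 CPM in co-cultured cells, and Gzmb, a granule protease of killer cells, had 1 count after co-culture. Of 25 T cell identity markers, 22 were below 1 CPM in both groups and the median was 0.8 counts per co-culture library. Of the 4 tested, Coro1a rose from 4.60 ± 0.717 to 6.96 ± 1.33 CPM, Lcp2 rose by 0.54 on the log2 scale, and the kinase gene Lck fell from 8.22 ± 1.34 to 5.23 ± 0.866 CPM (n = 5). The call of Lcp2 was lost in 7 of the 10 fits without 1 library (adjusted p 0.0119 to 0.109). The list was not called (camera, median 0.57, adjusted p = 0.506). Of 7 tested cytotoxic effector and activation markers, Ccl3 and Ccl4 rose and Ccl5 and Havcr2 fell. Havcr2 lost its call with the replicate number as a block (edgeR adjusted p = 0.0628). Ccl4 had 2 and 151 summed counts, a ratio of 78.9 (95% interval 21.5 to 657), and Ccl5 went from 118 ± 16.7 to 43.8 ± 6.03 CPM. This list was not called either (camera, median 0.09, adjusted p = 0.325).

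Cell cycle genes were higher. Of 26 tested, 23 rose and none fell, with a median of 0.71, the same counts adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, rose from 116 ± 8.15 to 248 ± 19.3 CPM (log2 fold change 1.10 ± 0.0636 SE, edgeR adjusted p = 5.04e-08), and the mitotic kinase gene Aurkb from 40.2 ± 1.42 to 75.7 ± 4.27 CPM (n = 5). Mki67, a proliferation marker, rose by 1.12 and the replication helicase gene Mcm5 by 0.76. The 3 members that did not pass were Ccnd1 (-0.04), Ccne2 (0.09) and E2f1 (-0.10). The list was higher by camera (adjusted p = 6.77e-14, and adjusted p = 0.0177 with an estimated correlation).

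**Figure D2:**
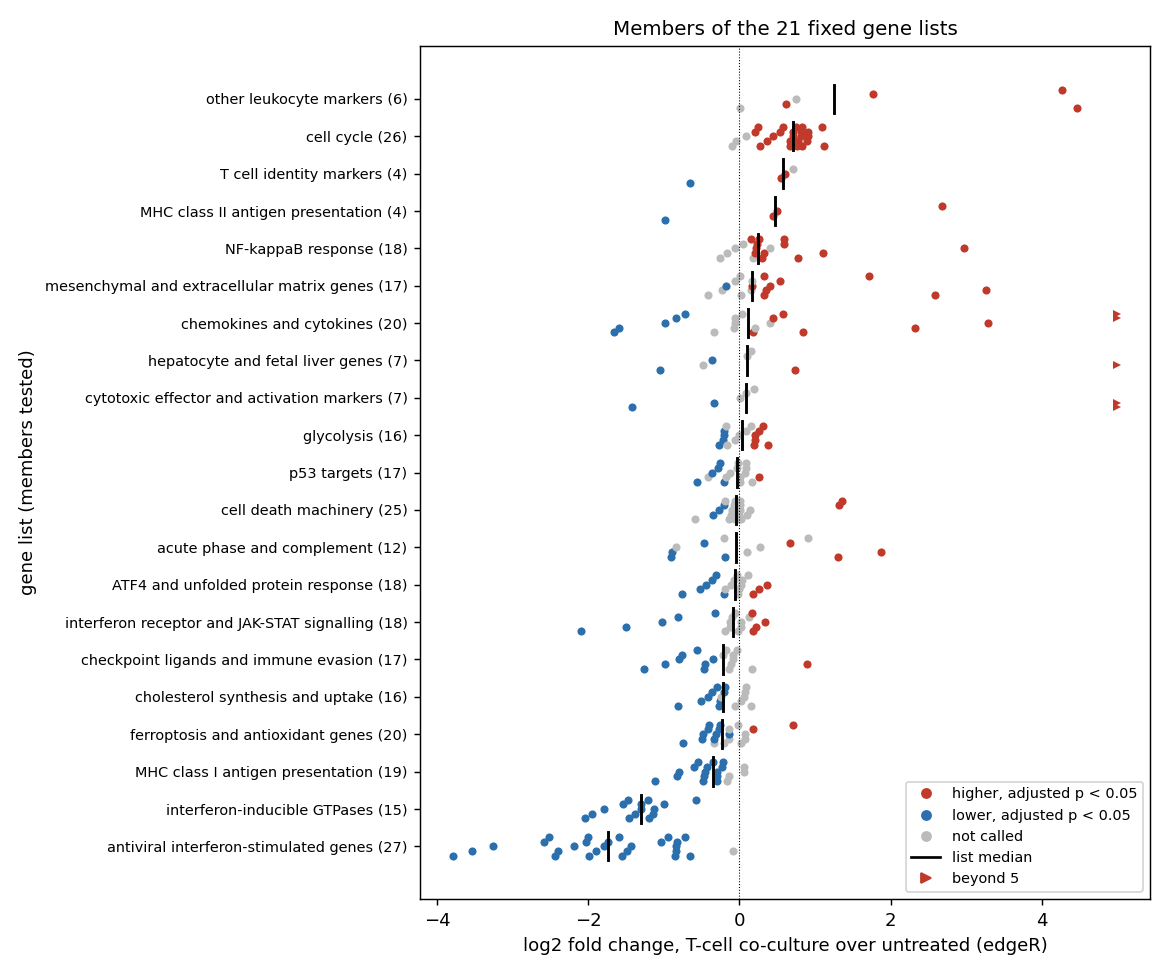
Log2 fold change (horizontal axis, co-culture over untreated, edgeR) of each tested member of the 21 fixed gene lists (rows, ordered by list median, number tested in brackets); red and blue points passed at an adjusted p of 0.05, grey points did not, triangles lie beyond 5 and black bars are medians. The antiviral genes lie lowest, with a median of -1.73, and the cell cycle genes sit at a median of 0.71.

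Genes of programmed cell death changed little. Of 25 tested, 2 rose and 3 fell. Nlrp3, an inflammasome sensor, rose from 2.22 ± 0.734 to 5.70 ± 0.824 CPM (n = 5, edgeR adjusted p = 0.000271), and Xiap, a caspase inhibitor, rose by 1.32 on the log2 scale (edgeR adjusted p = 0.0209). The untreated libraries of Xiap ranged from 7.83 to 46.0 CPM. Without untreated replicate 1, the highest of these, its log2 fold change was 2.05, and without untreated replicate 2 its call was lost (adjusted p = 0.0518). Gsdmd, whose product forms pores in pyroptosis, went from 242 ± 5.02 to 210 ± 6.01 CPM, and Mlkl fell by 0.27. Fas, the death receptor engaged by killer T cells, was at 5.43 ± 0.912 and 5.42 ± 0.735 CPM (edgeR adjusted p = 0.972). The list was not called (camera adjusted p = 0.368), and its median of -0.05 and mean of 0.03 differed in sign. Of 17 p53 targets, Zmat3 rose and Trp53inp1, Btg2, Ei24, Eda2r and Tigar fell. Trp53inp1 went from 53.9 ± 7.52 to 36.6 ± 4.06 CPM and Btg2 from 33.3 ± 2.38 to 26.0 ± 1.78 CPM (n = 5), and the list was not called (camera, median -0.03, adjusted p = 0.277). Eda2r and Tigar lost their calls in 8 and 7 of the 10 fits without 1 library, at adjusted p up to 0.0958 and 0.114.

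Genes of ferroptosis and antioxidant defence and of cholesterol supply were slightly lower. In the former list 10 of 20 fell (11 adjusted over the list alone) and 2 rose, with a median of -0.23. Slc7a11, the cystine transporter that feeds glutathione synthesis, fell from 106 ± 8.87 to 63.1 ± 5.51 CPM, and Tfrc, the transferrin receptor, rose from 82.6 ± 6.94 to 135 ± 7.91 CPM (n = 5), as did Hmox1 by 0.18 on the log2 scale. This list was called lower by camera (adjusted p = 0.0102), a call lost with an estimated correlation (adjusted p = 0.252). The call of Hmox1 was lost in 7 of the 10 fits without 1 library (adjusted p 0.0322 to 0.101). Of 16 cholesterol genes 9 fell and none rose, with a median of -0.22. Insig1, a sterol-regulated feedback gene, went from 156 ± 16.6 to 88.9 ± 3.49 CPM and Hmgcs1, an enzyme of the mevalonate pathway, from 187 ± 16.6 to 141 ± 6.10 CPM (n = 5). That list was lower by camera (adjusted p = 0.00829), also lost with an estimated correlation (adjusted p = 0.445).

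Glycolysis and stress-response genes moved both ways. Of 16 glycolysis genes, 6 rose, among them the phosphofructokinase genes Pfkl (0.38) and Pfkp (0.27), and Hk2, Pkm, Pgk1 and Slc2a1 fell (7 and 5 adjusted over the list alone). The list was not called (camera, median 0.04, adjusted p = 0.755). Of 18 genes of ATF4 and the unfolded protein response, 6 fell, among them the stress factor Ddit3, from 43.0 ± 6.23 to 25.5 ± 2.91 CPM, and Vldlr, from 98.4 ± 3.30 to 72.2 ± 3.93 CPM (n = 5), and the chaperone and quality-control genes Hyou1, Creld2 and Herpud1 rose. This list was not called (camera, median -0.05, adjusted p = 0.323). Herpud1 lost its call in 6 of the 10 fits without 1 library (adjusted p 0.0165 to 0.0594).

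Mesenchymal and extracellular matrix genes were higher on balance, with 9 of 17 higher and 1 lower (10 and 3 adjusted over the list alone) and a median of 0.17. Thbs1 had a log2 fold change of 1.72 ± 0.0843 SE (edgeR adjusted p = 1.38e-08), and Col1a2, a collagen gene, rose from 0.540 ± 0.155 to 3.27 ± 0.387 CPM (n = 5). Lox, which crosslinks collagen, rose from 0.108 to 1.08 CPM, and Col3a1 was the member that fell (-0.18). Lyz2 also rose after co-culture, by 4.27, and a source shared with the matrix genes was not tested. The list was higher by camera (adjusted p = 0.00499), a call lost with an estimated correlation (adjusted p = 0.0763).

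Liver genes were scarce in both groups. Alb, the albumin gene, had 0 counts in untreated cells and 4 after co-culture, all in replicate 2. Of 24 hepatocyte and fetal liver genes, 18 were below 1 CPM in untreated cells, and 7 were tested, of which Trf and Apoe rose and Rbp4 and Afp fell. Afp, the fetal liver marker alpha-fetoprotein, went from 20 ± 2.06 to 15.5 ± 0.863 CPM (n = 5, log2 fold change -0.36 ± 0.0817 SE, edgeR adjusted p = 0.00400), and Rbp4, a retinol carrier, from 7.13 ± 0.809 to 3.45 ± 0.325 CPM. Trf, the transferrin gene, had 2 and 274 summed counts, a ratio of 143 (95% interval 39.3 to 1188). Lyz2 rose after co-culture as well, and a source shared with Trf was not tested. The list was not called (camera, median 0.09, adjusted p = 0.927). Of 12 acute phase and complement genes, Saa3 rose from 3.16 ± 0.578 to 11.6 ± 1.32 CPM, C3 from 149 ± 7.21 to 236 ± 6.60 CPM (n = 5) and Hp by 1.30 on the log2 scale, and Lcn2, Cp and C1ra fell by 0.90, 0.47 and 0.20. That list was not called (camera adjusted p = 0.960), and its median of -0.05 and mean of 0.13 differed in sign.

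Among genes with a mean of at least 1 CPM, the largest falls outside the interferon genes were of genes without a list. Avil, an actin-binding protein of the villin family (chromosome 10, 127000709 to 127020994), fell from 47.4 ± 5.75 to 1.32 ± 0.383 CPM (log2 fold change -5.15 ± 0.153 SE, edgeR adjusted p = 2.65e-10), 35.6-fold lower. The secreted carbonic anhydrase gene Car6 went from 6.13 ± 1.56 to 0.148 ± 0.296 CPM, with 11 of its 12 counts after co-culture in replicate 2. The aldo-keto reductase gene Akr1b7 went from 8.86 ± 1.19 to 0.595 ± 0.226 CPM, the ATP-gated channel gene P2rx3 from 10.3 ± 0.954 to 0.956 ± 0.338 CPM, Sh2d6 from 2.91 ± 0.577 to 0.166 ± 0.129 CPM and Gdap1l1 from 2.65 ± 0.593 to 0.233 ± 0.155 CPM (n = 5 in each group).

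**Figure D3:**
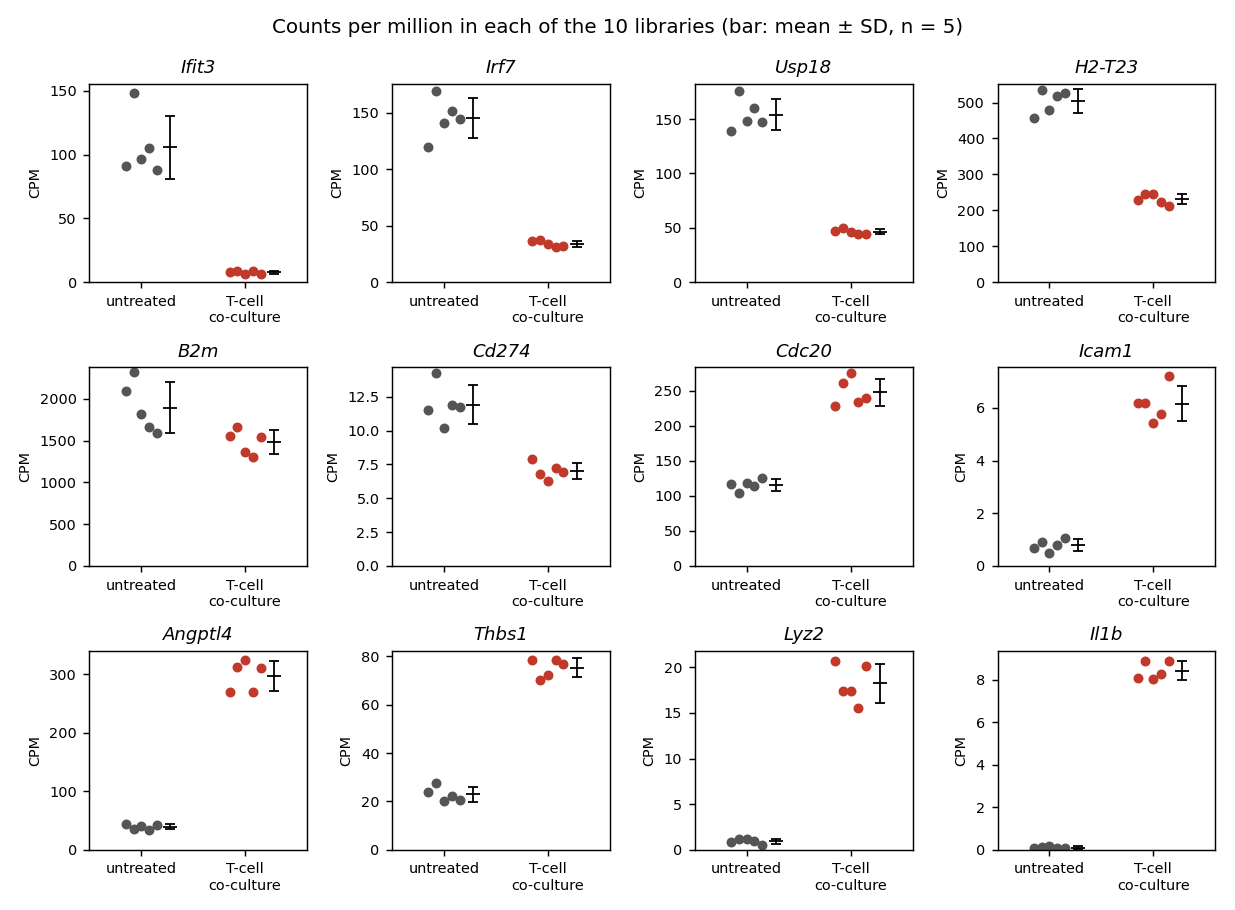
CPM (vertical axes, each from 0) of 12 named genes in each untreated (grey) and co-cultured (red) library, with the mean and SD of 5 libraries beside the points. Ifit3 lies near 106 CPM in untreated and 7.66 CPM in co-cultured libraries, and Angptl4 near 39.2 and 297 CPM.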

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

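All tests in this part on T cell markers, on panel genes near 0 and on genes lost at counting were chosen only after results were seen. The macrophage panel and the other tests of the patterns were written before their own values were looked at, but after the main results.

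In 26 of 286 groups of 5 libraries, the highest or lowest library lay far from the others, with a gap to the nearest library above 0.71 of the group's whole range. Chance flags about 1 in 20 groups, which is 14.3 here. Among untreated libraries the ratio was 1 for Ccl6 (replicate 5), Trf (replicate 4), Clec4e (replicate 3) and Ccl4 (replicate 2), each with 1 or 2 counts in that library and 0 in the others. Replicate 2 of the untreated cells was highest for Ifit3 (0.712), Ifit3b (0.746), Irgm2 (0.743) and Coro1a (0.815). Replicate 4 was lowest for Trp53inp1 (0.779) and Mki67 (0.773) and highest for the percent of ribosomal protein counts (0.717). Replicate 5 was highest for Inpp5d (0.822) and Cd68 (0.821) and lowest for Pdia3 (0.812), and replicate 1 was highest for Xiap (0.795) and lowest for Itgb2 (0.839). Among co-culture libraries, replicate 5 was highest for Csf2rb (0.927) and lowest for Col1a2 (0.818) and Irf1 (0.823). Replicate 2 was highest for Car6 (0.904) and replicate 4 for C3 (0.759). Replicate 1 was lowest for Slc15a3 (0.765) and highest for Ccne2 (0.787), and replicate 3 was lowest for Vcam1 (0.754) and C1ra (0.715) and highest for Ncapd2 (0.754).

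The rise of myeloid genes from near 0 was weighed first. Carry-over of the added T cells was argued against by a median of 0.8 counts per co-culture library over 25 T cell markers, and a greater depth after co-culture by the totals, which averaged 14797200 counts there and 15461200 in untreated cells. Thinning every library to 12922263 counts left a median log2 difference of 6.97 for 7 myeloid genes, which adds nothing, since these genes were picked by their rise. For RNA from myeloid cells, 53.3% of the tested macrophage panel rose, between the bounds of 60% and 30% set for it, so that test was undecided. Of the panel genes under 0.2 CPM in untreated cells, 91.3% (21 of 23) had more counts after co-culture. For 17 of these 23, every co-culture library lay above every untreated library. This choice of genes, made after their values were seen, leaves little room for a fall. A gene could still have stayed near 0, as Cd3e and Cd8a did. Most of these panel genes rose, but the source of their RNA was not tested and the explanation stays open.

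For the fall of interferon-stimulated genes, weighed second, scaling was argued against by the antiviral list, whose median was -1.73 under the scaling that brought it nearest to 0. Dilution of the hepatoma RNA as the source of the whole fall was argued against, since it lowers genes that other cells lack by 1 factor, while members of this list ranged from -3.78 to -0.08 and 23 of 26 cell cycle genes rose. The median over all tested genes with library totals as the scaling, 0.0414 against -1.70 for the antiviral list, decides little by itself, since scaling to totals centres it, and a small share of dilution was not excluded. An exchange of the group labels could not be decided, since the tested macrophage panel had a median of 0.398, between the bounds of 0 and 0.5. That median also covers genes already abundant in untreated libraries, such as Itgb2 at 156 to 183 CPM. In this panel 8 tested genes rose and 1 fell. This direction argues against an exchange only if the leukocyte RNA came with the added cells, which was not tested. An effect of the co-culture itself was not tested apart from these.

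The near absence of hepatocyte genes was weighed last. Loss of genes at counting could not be decided, since the share of the list under 1 CPM in untreated cells, 75%, only restates the pattern. Cells of another lineage could not be told apart from hepatoma cells. The highest share of a panel at 5 CPM or more in untreated cells was 40%, in the general epithelial and fibroblast panels. The general epithelial panel is not specific to a lineage other than liver, so its share cannot separate the possibilities. Of the hepatocyte list 12.5% reached 5 CPM, 3 of 24 genes, among them Afp. No biological explanation was tested, since the design has 1 cell line.

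Chance as the source of the counts was tested with 100 of the 126 splits of the libraries into 5 and 5. The 2204 higher genes, the 2044 lower genes and the 151 and 200 at least 2-fold were reached by 1 of the splits each, the real one, and the highest count of any other split was 1. The 10 called lists were reached by 4 splits, with 11 as the highest other count, and the 3 others kept 4 of the 5 libraries of each group together. Lists were also called where the groups were more mixed. As many as 8 lists were called in a split that kept only 3 of the 5 together and called 0 genes. The number of lists called at the preset correlation therefore says less than the gene counts.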

How the results depend on the processing

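The scalings for the list results were tried only after the data were seen. Without a low-count filter 330 genes were at least 2-fold higher, where more genes with few counts were tested, and testing only genes with at least 1 CPM in untreated cells left 52 by construction. With limma on log2(FPKM + 1), 27 were 2-fold higher and 72 2-fold lower, and the added 1 shrinks changes of scarce genes. The called lists went from 10 to 5 with an estimated correlation, and the cause was not tested. With fry they went to 17. fry does not compare a list with other genes, and 33.5% of all tested genes were called. Every other alternative kept the counts within 1.5 times. Without 1 library, 1849 to 2128 genes were higher, 1813 to 2093 lower, 148 to 175 2-fold higher and 197 to 221 2-fold lower, with 10 to 10 lists. With the replicate number as a block, 1762 genes were higher, 1625 lower, 143 and 198 2-fold, and 10 lists were called; same-numbered libraries had correlations of -0.0986 to 0.0507, and 1 of 10 correlated best with its own number. The block left Ifngr2, Havcr2, Lcp2, Hmox1, Herpud1, Eda2r and Tigar short of the threshold (edgeR adjusted p from 0.0591 to 0.101) and changed no other call of a named gene. Of 2934 values of named genes under alternatives, 2865 kept their call, 56 were weaker, 13 stronger and 0 reversed, and all changes fell among genes named after their values were seen. The rule for the others took mostly the largest changes and the smallest p-values, so their stability was largely set by that choice. Of 357 list values, 344 kept their call, 6 were weaker, 7 stronger and 0 reversed. The difference in library totals was -663982 counts, and -665444 over tested genes only. Calls were 51.9% higher, and 60.3% with FPKM. Genes under 0.175 to 0.232 CPM in a library are below what depth resolves.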

Other observations

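The 6 lists in this part were chosen only after results were seen.

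Fatty acid oxidation genes and PPAR targets were higher after co-culture. Of 28 tested, 16 rose and none fell (17 rose and 1 fell adjusted over the list alone), with a median of 0.30. Cpt1a, which carries fatty acids toward mitochondrial oxidation, rose from 108 ± 8.29 to 272 ± 12.7 CPM (n = 5, edgeR adjusted p = 5.13e-09), beside Angptl4, the carnitine carrier gene Slc25a20 (0.92) and the lipid droplet gene Plin2 (0.50). Cpt1b rose by 2.66, with untreated libraries spread from 0.0753 to 1.81 CPM, and Cd36 rose by 4.70 from at most 0.187 CPM. Cd36 is also a macrophage gene. The macrophage genes Lyz2 and Adgre1 rose after co-culture too, by 4.27 and 4.47, and a shared source was not tested. The list was higher by camera (adjusted p = 1.65e-06, and adjusted p = 0.0282 with an estimated correlation).

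Genes of condensin, the spindle and the kinetochore were also higher, with 31 of 32 risen and none fallen (32 adjusted over the list alone) and a median of 0.76 (camera adjusted p = 4.96e-20, and adjusted p = 0.0171 with an estimated correlation). Ncapd2, a condensin subunit, went from 129 ± 12.5 to 267 ± 11.3 CPM (n = 5). Lysosome genes were not called as a list (32 tested, 5 rose and 10 fell, 6 and 10 adjusted over the list alone, camera, median -0.02, adjusted p = 0.166), although Ctsd, a lysosomal protease, fell from 2942 ± 228 to 1539 ± 94.6 CPM (n = 5).

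Of 35 macrophage genes 15 could be tested, 8 rose and 1 fell, with a median of 0.40 (camera adjusted p = 0.000399, and adjusted p = 0.0171 with an estimated correlation). All 3 tested genes of a neutrophil panel of 12 fell (median -0.90, camera adjusted p = 0.00298, and adjusted p = 0.0282 with an estimated correlation). Of a fibroblast and endothelial panel 7 of 14 were tested, 2 rose and 1 fell (median 0.25, camera adjusted p = 0.687). Several panel genes were abundant in untreated cells, Gpnmb at 520 ± 27.1 CPM, Padi4 at 249 ± 12.7 CPM and Itgb2 at 175 ± 10.8 CPM (n = 5).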
